A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

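Total RNA from biofilms of an E. coli MG1655 cra deletion mutant and its wild type was labelled with Cy3 and Cy5 and hybridised on 2 Agilent arrays, per the labels. Cells were scraped off CFA agar plates after 48 h at 26 °C and kept in 500 μl RNAlater, per the labels' protocols. The dyes were swapped between the duplicates, per the labels: the mutant was in Cy5 on array 1 and in Cy3 on array 2. Both arrays form 1 group in which each array compares the strains, so no paired fit between groups applies. Both lay on the same slide, so slide could not be tested as a batch.

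Spot intensities were deposited as scanner output of Agilent Feature Extraction 9.5.3.1, per the file headers, with mean signal and median local background per spot and dye, not corrected. The processed signal columns, also intensities, were background-subtracted, detrended and dye-normalized (linear, then lowess) by that program, per the file headers. The LogRatio column is the log10 of red over green processed signal, per the file headers. The authors' value table holds log10 ratios: for all 15744 spots its column equals LogRatio on array 1 and minus LogRatio on array 2 exactly, so both columns are mutant over wild type, with medians over all spots of 0.047 and -0.0048 on the log10 scale and no further centring. The labels name Agilent Feature Extraction as the processing tool.

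The array held 15744 spots with probes of 60 bases placed on NC_000913.2 (MG1655), of which 536 were control spots. There were 10459 coding probes with a gene ID, for 4060 genes, 369 coding probes without a gene ID, and 2190 sense and 2190 antisense probes of noncoding regions. The latter sets were left out of the tests and are described in the closing section. Probes of other E. coli genomes numbered 0. Symbols came from a RefSeq table of assembly ASM584v2 through the gene ID, which matched 4054 genes; the other 6 kept the file's name, and 461 symbols differ from the file's (fruR in the file is cra, hepA is rapA, pps is ppsA). Coordinates are those of the files.

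The mean signals were background-corrected in limma 3.58.1 (R 4.3.3) by normexp with an offset of 50, and normalized within each array by loess with control spots at weight 0. Spots with an outlier mark were left out (3 on array 1 and 2 on array 2) and saturated spots were kept (7 in the mutant channel of array 1 and 16 in the wild-type channel of array 2). Probes of a gene were averaged; 35 genes had 1 probe, 1651 had 2 and 2374 had 3, and in 1790 of the 4025 genes with over 1 probe the probes differed in sign. The offset draws the ratios of dim genes towards 0, so their folds are understated. The log2 ratio of array 2 was turned, and lmFit and eBayes tested the mean against 0, with Benjamini-Hochberg adjustment over 4060 genes, 1 residual degree of freedom and a prior of 3.29. A dye term would have left no residual degree of freedom. A gene not well above background in the mutant on either array is read as at least N-fold lower: the wild-type mean against the higher of its own signal and the lowest signal well above background, per channel after loess and Aquantile. This bound is on the mean of both arrays and leaves out their spread, so an array alone can lie below it. With the lowest such signal as floor, the bounds lie close to the ratios themselves.

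Before the data were examined, 25 gene lists were written from general knowledge of E. coli, and the curli list also with prior knowledge of the study, with 563 members of which 555 were measured, and were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. The named genes followed a rule fixed at the same time: cra; up to 12 passing genes with the highest and 12 with the lowest mean and the same sign on both arrays, filled, where fewer than 6 passed, from genes at least 2-fold apart on both arrays; up to 4 members of each list; and the curli genes, fructose genes and a set of genes known as Cra targets or neighbours. Alternatives fixed then were normexp with an offset of 10, no background correction, Agilent's processed signals, the authors' value table, median centring, loess on gene probes only, Aquantile between arrays, probes well above background, the brightest probe, marked spots kept, unturned arrays, eBayes with an intensity trend, robust eBayes, camera with an estimated correlation, camera on ranks, fry, and each array alone. Another, without the genes from rluA to cra, was chosen after seeing the data.

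The functions were tested on simulated arrays with the real brightness, a dye curve and spreads drawn from the fitted prior, for the comparison of cra mutant with wild type over 4060 genes. Of 50 genes changed by 1 on the log2 scale 31 were called, and of 50 each changed by 2, 3 and 5 all 50 were called. Of 3860 unchanged genes 17 were called. The changed genes left out the dimmest genes and far outnumbered the 9 genes that passed in the real comparison, which eases the adjustment. These shares do not carry over to the real comparison, where csgA at -4.88 did not pass. All changed genes had the right direction, and a change of 5 came out at 4.59. Among 25 lists, 1 list of 17 genes shifted by 1 was called and 0 others. The noise of each simulated gene was drawn independently, so this does not test how camera does where genes of a list vary together.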

Results

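RNA of an Escherichia coli K-12 MG1655 mutant lacking cra was compared with RNA of its wild type on 2 arrays, each of which held both strains. Cra, also called FruR, is a DNA-binding regulator of carbon metabolism that lets go of its targets when fructose phosphates bind it. Both strains had grown as biofilms on plates of CFA agar, a medium on which curli and fimbriae are commonly studied, for 48 h at 26 °C. The mutant carried the dye Cy5 on array 1 and Cy3 on array 2, so that a dye effect cancels in the mean. All ratios are cra mutant over wild type on the log2 scale, given as mean ± SD (n = 2). Of 10459 gene probes, 90.6% lay well above background in the mutant and 54.8% in the wild type on array 1, against 78.2% and 94.6% on array 2. The number of arrays limits the precision, and nothing in the labels says that the duplicates were separate cultures. The limma p-values therefore measure the spread between these arrays, which may be technical, together with a prior spread pooled over genes. The camera p-values set the genes of a list against the other genes. At the small preset inter-gene correlation they treat genes of the same operon as nearly independent.

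The targeted gene came first as a check of the labels. The ratio of cra (positions 88028 to 89032 of NC_000913.2) was -1.93 ± 0.39, with -1.66 on array 1 and -2.21 on array 2, and its adjusted p in limma was 0.10. It passed in 4 of 12 alternatives and ran to -4.38. All 3 cra probes were lower in the mutant on both arrays, with means of -2.04, -2.10 and -1.66. In the mutant, 2 of the 3 probes stayed well above background on array 1 and 1 of 3 on array 2, and which part of cra was deleted is not given in the sources used here. The values do not go against the strain labels.

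The comparison of the strains asked which transcripts differ in a biofilm between the cra mutant and its wild type. The genes of fructose uptake rose most: fruB by 7.91 ± 0.59, fruK by 6.48 ± 0.39 and fruA by 5.83 ± 0.36 on the log2 scale. The wild-type signal of fruB was well above background on array 2 only, and its ratio ran from 7.75 to 9.71 over the alternatives. These genes form an operon (fruB at positions 2260387 to 2261517) that encodes the fructose phosphotransferase components and 1-phosphofructokinase. Also higher were epd, which encodes erythrose-4-phosphate dehydrogenase, by 3.83 ± 0.02, and prpE, for propionyl-CoA synthetase, by 2.20 ± 0.09. The curli regulator csgD fell by 3.25 ± 0.35 and the curli secretion factor csgE fell by 2.70 ± 0.03. The leucine synthesis gene leuD fell by 2.91 ± 0.19, and yabI, which encodes an inner membrane protein of the DedA family, fell by 2.67 ± 0.31. In the mutant leuD was not well above background on either array, which makes it at least 7.44-fold lower. Over the alternatives leuD ran to -6.50 and yabI to -6.66. The probes of fruA spread over 2.12 log2 units, all of them higher in the mutant.

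In limma, 9 of 4060 genes passed an adjusted p of 0.05, 5 of them higher and 4 lower in the mutant, and 536 had an unadjusted p under 0.05. Adjusted p in limma was 0.0051 for fruB, fruK and fruA, 0.0080 for epd, 0.025 for csgD, csgE and leuD, and 0.040 for prpE and yabI, each in the same direction on 2 of 2 arrays. At least 2-fold apart in the same direction on both arrays, with no test, were 65 genes, 34 higher and 31 lower. Array 1 alone gave 325 such genes and array 2 alone 104. Both arrays with median centring gave 47, 17 higher and 30 lower. Among the 65, the largest ratios that did not pass were 3.36 ± 1.96 for ymdF, 2.34 ± 0.64 for adhE, 2.15 ± 0.52 for thiE, 2.15 ± 0.51 for thiF, 2.07 ± 0.45 for thiS, 2.04 ± 0.39 for prpC and 1.91 ± 0.23 for bdcA. Of these genes ymdF, bdcA, thiE, thiF and thiS passed in 4 of 12 alternatives, and adhE and prpC in 3. Over these thiE ran to 4.04, thiF to 3.78, thiS to 3.34 and bdcA to 3.98. For thiE, thiF and bdcA the wild type was well above background on array 2 only. The lowest that did not pass, beside the curli genes below, were -2.66 ± 0.46 for setA, -2.24 ± 0.31 for rapA, -2.16 ± 0.90 for yceQ and -2.12 ± 0.18 for rluA. Of these setA, rapA and rluA passed in 5 of 12 alternatives and yceQ in 3, and setA ran to -6.86, rapA to -4.34 and rluA to -3.20. In the mutant setA was not well above background on either array. Its mean fall is read as at least 5.97-fold, though array 2 alone gave a smaller fall, at -2.33. Across genes, which are not independent replicates, the ratios of the arrays correlated with Pearson's r of 0.55 and Spearman's rho of 0.37. The same sign on both was seen for 61.0% of genes. This agreement depends on the loess step, since with median centring Pearson's r was -0.34. In limma 48 genes then had an unadjusted p under 0.05. The count of passing genes ran from 6 without background correction, 4 higher and 2 lower, to 115 on Agilent's processed signals. The authors' value table gave 34, 15 higher and 19 lower. Probes well above background gave 13, 5 higher and 8 lower. Calls of prpE and yabI were lost without background correction, with median centring, with loess on gene probes and with the brightest probe. The call of csgD was lost with the brightest probe, csgE with median centring and leuD without background correction.

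**Figure D1:**
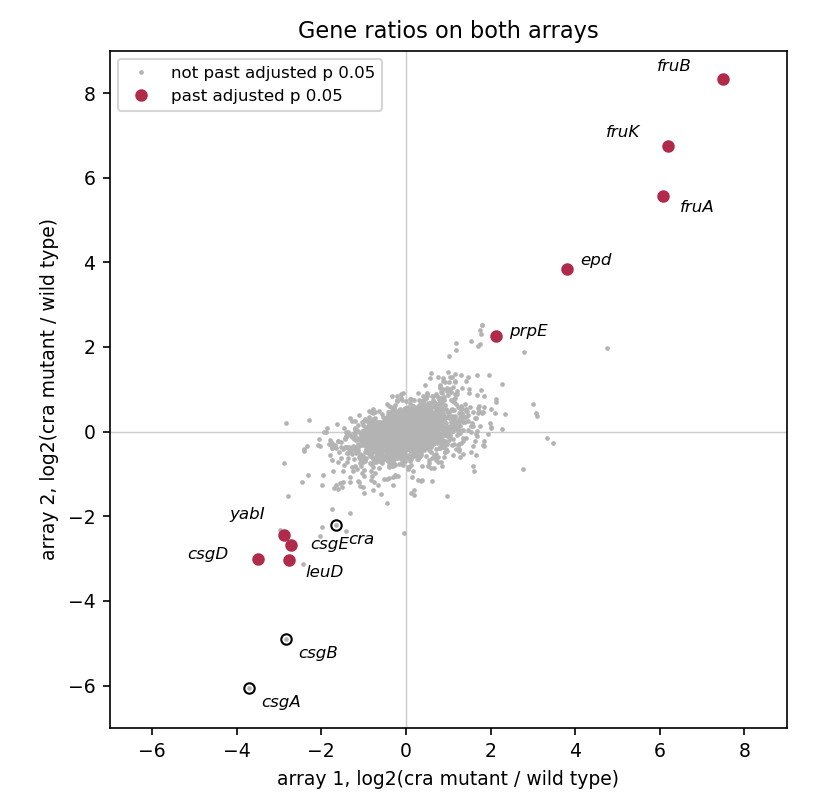
Each point is a gene, with its log2 ratio of cra mutant over wild type on array 1 (horizontal) and array 2 (vertical); filled red points are the 9 genes past an adjusted p of 0.05 in limma and open circles mark cra, csgA and csgB, which did not pass. The fructose genes lie at the upper right, up to 7.91 for fruB as a mean, and csgD and csgE at the lower left.

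Curli are amyloid surface fibres that hold biofilm cells together, and are made from csgA and csgB under control of csgD. Of the 7 curli genes, csgD and csgE fell and 5 did not pass the test over all genes, while 6 fell when adjusted over the list alone. Of those 5, csgC passed in 7 of 12 alternatives, csgA and csgB in 5, csgF in 4 and csgG in 0, and csgC ran to -5.23 and csgF to -3.58. All 7 had ratios below 0 on both arrays, except that csgG was above 0 on array 1 on the processed signals, in the value table and with median centring. The major subunit csgA (positions 1103670 to 1104125) stood at -4.88 ± 1.67, from -3.70 on array 1 to -6.06 on array 2, and the nucleator csgB at -3.87 ± 1.47, with adjusted p in limma of 0.11 and 0.12. The ratio was -2.78 ± 0.49 for csgC and -1.89 ± 0.66 for csgF. The outer membrane pore gene csgG differed between the arrays, with -0.04 on array 1 and -2.41 on array 2. The list mean was -2.94 ± 0.80, and camera put the list below the other genes with adjusted p = 7.9e-10 (adjusted p = 0.69 with an estimated correlation). The curli list was chosen with prior knowledge of the study, so it is not independent evidence of its direction.

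The list of sugar uptake and glycolysis genes known to be repressed by Cra held 22 measured genes. Of these 4 rose (fruB, fruK, fruA and epd), none fell and 18 did not pass, while adjusted over the list alone 9 rose and 1 fell. Among the members that passed only when adjusted over the list alone, ratios were 2.34 ± 0.64 for the alcohol dehydrogenase gene adhE, 1.69 ± 0.80 for fbaA, 1.38 ± 0.11 for pgk, 1.32 ± 0.03 for gpmM and 1.25 ± 0.33 for gapA, 4 genes of glycolysis, and -1.19 ± 0.18 for the aconitase gene acnB. The glycolytic genes pfkA and pykF, at 0.28 ± 0.01 and 0.59 ± 0.44, the mannitol transporter gene mtlA at 0.55 ± 0.32 and edd at 0.03 ± 0.06 did not pass. Over all genes adhE and gpmM passed in 3 of 12 alternatives, fbaA in 2, pgk and acnB in 1 and gapA in 0. On the chromosome fbaA, pgk and epd lie next to each other, and the fructose genes share an operon. The members that were higher are therefore not independent of each other. The list mean was 1.51 ± 0.12 and the median 0.57, so the mean leans on the 4 genes that rose. In camera the list stood above the other genes with adjusted p = 4.3e-09 (adjusted p = 0.69 with an estimated correlation).

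Of 10 measured genes known to be activated by Cra, none passed over all genes tested, while 5 fell when adjusted over the list alone. Those were ppsA, which encodes phosphoenolpyruvate synthase, at -1.78 ± 0.05, the malate synthase gene aceB at -0.95 ± 0.06, fbp at -0.80 ± 0.48, acnA at -0.62 ± 0.03 and pck at -0.58 ± 0.24. Over all genes ppsA passed in 4 of 12 alternatives and ran to -2.79, and the other 4 passed in 0. The isocitrate lyase gene aceA at -0.27 ± 0.39, icd at 0.26 ± 0.80 and the oxidase gene cydA at 0.02 ± 0.03 passed neither way. The list mean was -0.54 ± 0.08, below the other genes in camera with adjusted p = 0.00046 (adjusted p = 0.69 with an estimated correlation).

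**Figure D2:**
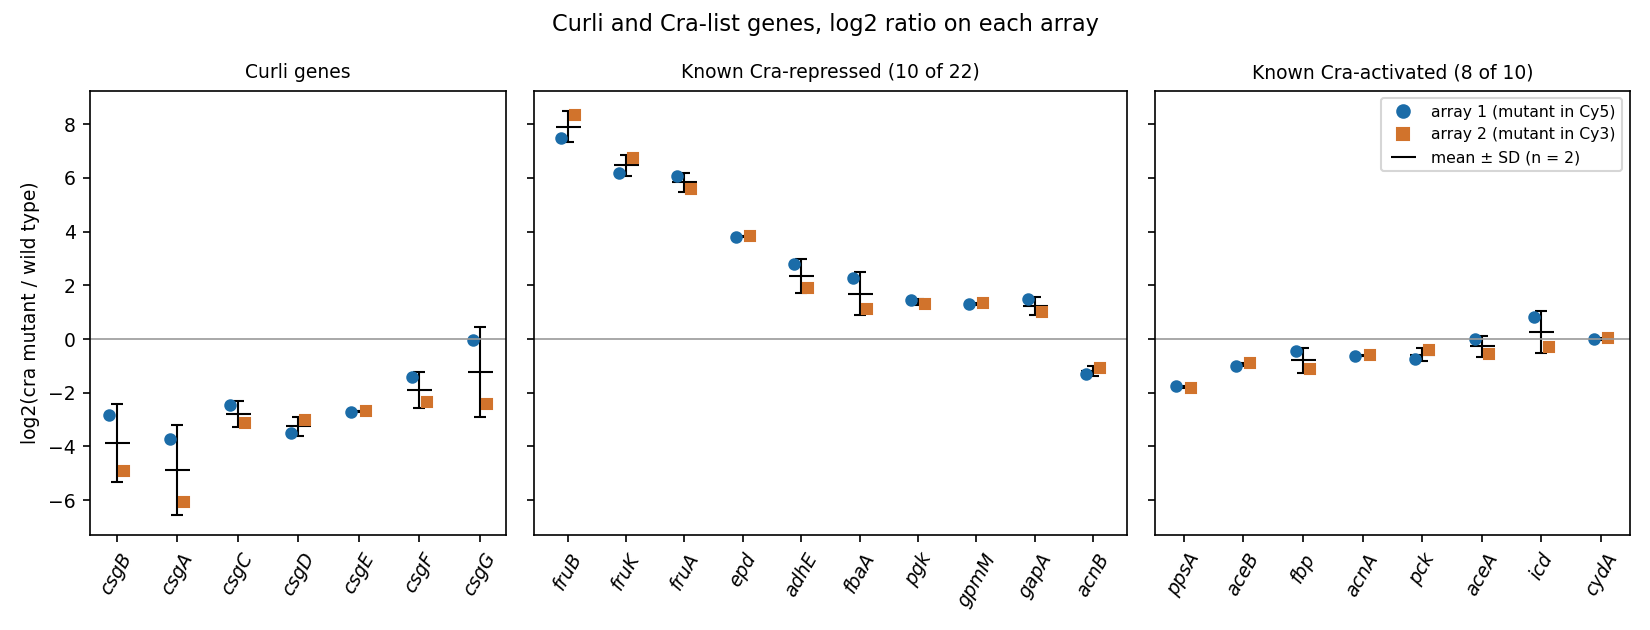
Log2 ratio of cra mutant over wild type (vertical axis) for the curli genes and for named members of the lists of genes known to be repressed or activated by Cra; circles are array 1, squares array 2, and black marks the mean ± SD (n = 2). The means of the 7 curli genes lie below 0, at -4.88 for csgA and -1.22 for csgG as means, and the fructose genes reach 7.91.

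Other lists fixed in advance also stood apart from the rest of the genes in camera. Of 18 measured tricarboxylic acid cycle genes none passed over all genes, while 4 rose and 2 fell when adjusted over the list alone. Those included prpC, which encodes the methylcitrate synthase of propionate breakdown, at 2.04 ± 0.39, sucB at 0.68 ± 0.03 and sucA at 0.66 ± 0.05 above 0, and acnB at -1.19 ± 0.18 below 0. The list mean was 0.25 ± 0.02, with adjusted p = 0.032 in camera (adjusted p = 0.69 with an estimated correlation). The call was also lost with an offset of 10, without background correction, on the processed signals, in the value table, with median centring, with the brightest probe and on ranks. Of 14 measured acid resistance genes none passed over all genes and 4 fell when adjusted over the list alone, namely slp at -1.34 ± 0.21, hdeD at -1.62 ± 0.52, gadB at -0.92 ± 0.17 and gadX at -0.69 ± 0.01. Over all genes slp and hdeD passed in 3 of 12 alternatives. The mean of that list was -0.57 ± 0.16, with adjusted p = 3.2e-05 in camera (adjusted p = 0.69 with an estimated correlation).

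None of the 53 measured ribosomal protein genes passed, over all genes or adjusted over the list alone, but 35 lay above 0 and 8 below 0 on both arrays. Examples were rplA at 1.41 ± 1.02, rplK at 1.27 ± 0.57 and rpsC at 1.17 ± 0.80. The list mean was 0.38 ± 0.34, above the other genes in camera with adjusted p = 4.6e-06 (adjusted p = 0.69 with an estimated correlation), and with median centring the call was lost and 0 of the 53 lay above 0 and 3 below 0 on both arrays. None of 17 heat shock genes passed either way, with dnaK at 0.84 ± 0.65, htpX at 0.71 ± 0.37 and groS at 0.75 ± 1.53. Their mean was 0.35 ± 0.24, with adjusted p = 0.0024 in camera (adjusted p = 0.69 with an estimated correlation), lost with median centring and on the processed signals. None of 52 flagellar and chemotaxis genes passed either way, with flgK at -0.45 ± 0.30 and flgL at -0.42 ± 0.23. Their mean was -0.12 ± 0.05, with adjusted p = 0.016 in camera (adjusted p = 0.69 with an estimated correlation), lost with median centring, without background correction and with the brightest probe.

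Genes near cra on the chromosome stood lower in the mutant as well. Of 13 measured genes of branched-chain amino acid synthesis leuD fell and 12 did not pass, while 5 fell when adjusted over the list alone, among them leuC at -0.99 ± 0.23, leuB at -1.03 ± 0.62, leuA at -0.85 ± 0.18 and ilvH at -0.69 ± 0.21. Over all genes leuC passed in 4 of 12 alternatives and leuB, leuA and ilvH in 3, and they ran to -3.68, -3.79, -2.88 and -3.56. The list mean was -0.48 ± 0.26, with adjusted p = 0.011 in camera (adjusted p = 0.72 with an estimated correlation), lost on ranks. Of 8 measured neighbours of cra none passed either way, and 7 had means below 0. Before cra, leuO stood at -0.56 ± 0.01, ilvH at -0.69 ± 0.21 and ilvI at -0.28 ± 0.21. After cra, rsmH stood at -0.47 ± 0.03, ftsI at -0.30 ± 0.40, ftsL at -0.19 ± 0.09, murE at -0.19 ± 0.24 and mraZ at 0.16 ± 0.31. Over all genes leuO passed in 2 of 12 alternatives and ran to -2.09, ilvI passed in 1 and ran to -1.98, and the genes after cra passed in 0. Their mean was -0.31 ± 0.02, with adjusted p = 0.013 in camera (adjusted p = 0.69 with an estimated correlation), lost with median centring. The 21 measured genes from rluA (start 59687) to cra (end 89032) all had mean ratios below 0, as they did under each other signal or normalization setting that kept them, and 20 of them were below 0 on both arrays. The genes leuD, yabI, setA, rapA and rluA and 6 of the 13 branched-chain genes lie in this stretch. In the mutant 12 of the 21 were not well above background on either array, so that their ratios are read as bounds. On the mean of both arrays these bounds were 2.04-fold for leuB, 1.60-fold for ilvH and 1.46-fold for leuO, close to the ratios themselves. Single arrays gave smaller falls for leuB (-0.59 on array 1) and ilvH (-0.54 on array 2). For leuB the wild type was well above background on array 2 only, so its bound rests partly on an array without such signal. Without its 21 genes, an alternative chosen after seeing the data, the branched-chain list had a mean of 0.07 and the neighbours of cra a mean of -0.20, with adjusted p in camera of 0.82 and 0.23. The counts became 6 passing genes, 4 higher and 2 lower, with prpE no longer past the test, and 58 genes at least 2-fold apart on both arrays.

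**Figure D3:**
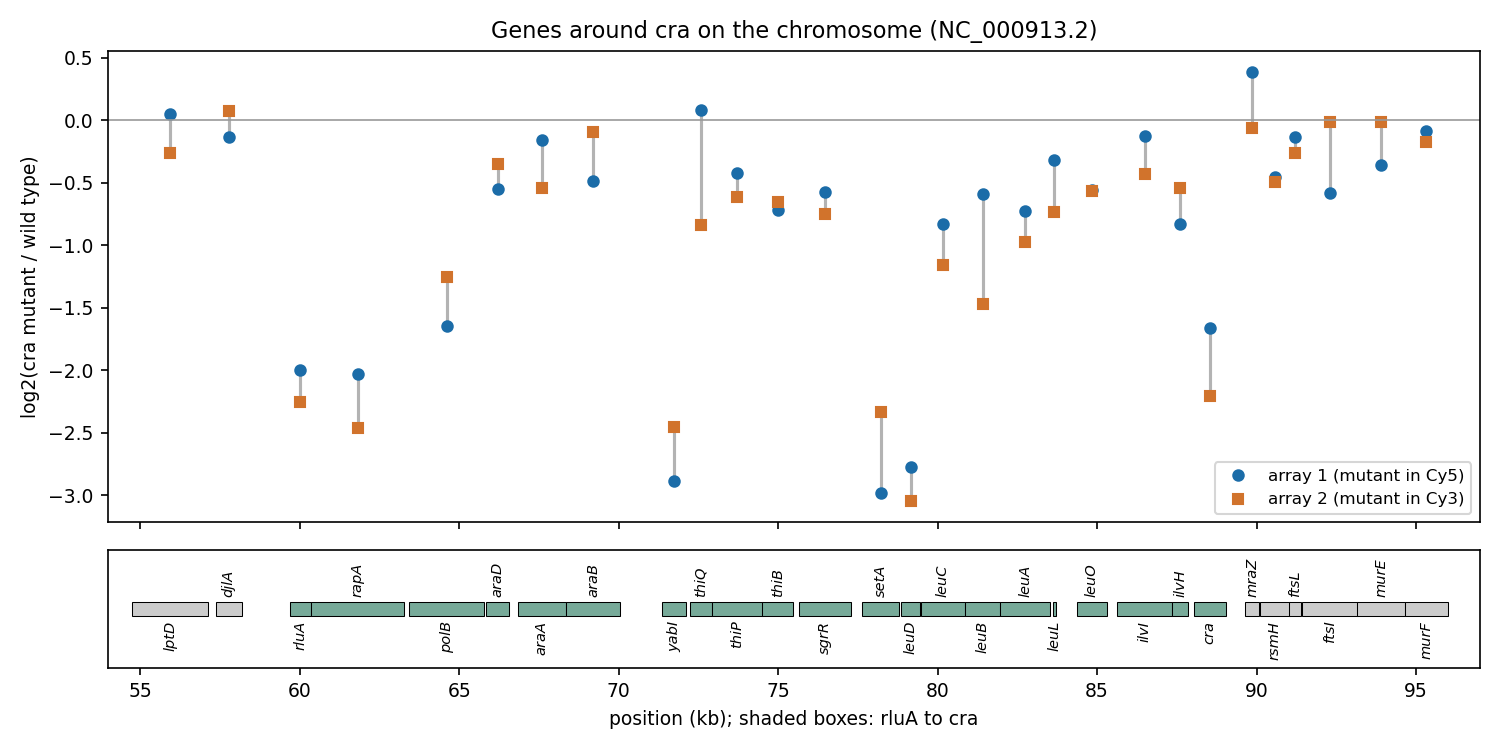
Log2 ratio of cra mutant over wild type (vertical axis) against position on NC_000913.2 in kb for the measured genes around cra, with circles for array 1 and squares for array 2, and gene positions as boxes below. The 21 shaded genes from rluA to cra have means from -2.91 (leuD) to -0.28 (ilvI), and beyond cra rsmH has a mean of -0.47 and mraZ of 0.16.

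Other matrix and biofilm lists did not pass in camera, and no member passed over all genes. In the alternatives dgcC passed in 2 of 12 and ran to -1.86, bdcA passed in 4 and ran to 3.98, and hha passed in 2. The means were -0.19 for cellulose synthesis and export (adjusted p = 0.17), with the diguanylate cyclase gene dgcC at -0.71 ± 0.02 and the export gene bcsC at -0.42 ± 0.39, 0.02 for cyclic di-GMP synthesis and breakdown (0.79), -0.02 for poly-N-acetylglucosamine (0.89), -0.02 for colanic acid (0.79) and -0.01 for type 1 fimbriae (0.94), with fimH at -0.54 ± 0.53. Among 24 biofilm regulators (mean 0.19, median -0.01, adjusted p = 0.31) none passed over all genes, while 5 rose and 1 fell when adjusted over the list alone. Those included bdcA, known for a role in biofilm dispersal, at 1.91 ± 0.23, hha at 1.38 ± 0.57 and bssR at 1.02 ± 0.19, and ariR at -1.16 ± 0.21. For bdcA the wild type was well above background on array 2 only. The remaining lists also did not pass, with means of 0.13 for arginine, histidine, methionine and tryptophan synthesis, 0.21 for cold shock, -0.10 for anaerobic respiration and fermentation, -0.12 for indole and quorum sensing, 0.07 for prophage genes, -0.07 for other phosphotransferase and sugar transport genes, -0.02 for RpoS-dependent stress genes, -0.02 for respiration and ATP synthase and 0.01 for iron uptake. For type 1 fimbriae the median, 0.02, and the direction in camera were above 0 while the mean was below, and for the biofilm regulators the median was below 0 while the mean and the direction in camera were above. Of the 25 lists 10 passed in camera, 4 above and 6 below the other genes, and none passed with an estimated correlation at 1 residual degree of freedom.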

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

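The counts in this part were all chosen after the values were seen, and none of them was tested. Of the intergenic probes, which the comparison of genes leaves out, 39.4% were well above background in the mutant on both arrays. In the wild type 22.2% were, and no more than 2 of the 77 negative control spots were in any channel. The order of the strains turned between the arrays, with 60.3% in the mutant and 22.6% in the wild type on array 1 against 40.2% and 67.8% on array 2, so these shares give no difference between the strains. At least 2-fold apart in the same direction on both arrays were 36 intergenic probes, 24 higher and 12 lower in the mutant. Several lay beside genes named in the report. The antisense probe between csgD and csgB (positions 1102420 to 1103173) had a ratio of -2.57 ± 0.29, and the sense probe between rapA and polB had -4.38 ± 2.80. The antisense probe between adhE and ychE (positions 1297345 to 1297820) had 2.99 ± 0.65, that between fbaA and pgk 2.08 ± 0.04, and that between fruB and setB 2.01 ± 0.37. The sense probe between prpB and prpC had 1.62 ± 0.63. The strand of these probes was not set against that of the genes beside them, so none is read as RNA antisense to a gene. Of the coding probes without a gene ID, 43.1% were well above background in the mutant on both arrays and 21.1% in the wild type. The order turned here too, with 66.7% in the mutant and 21.1% in the wild type on array 1 against 44.2% and 74.8% on array 2. Of these probes 0 were at least 2-fold apart on both arrays.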

How the results depend on the processing

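The alternative without the genes from rluA to cra was chosen after the result was seen; the others were fixed. The genes fruB, fruK, fruA and epd passed in limma in all 12 alternatives counted for single genes, which leave out the unturned arrays. The 12 are those of signal, normalization and probe choice, marked spots kept, eBayes with an intensity trend and robust eBayes. Of them leuB and ilvI were tested in 11. Aquantile, marked spots kept and robust eBayes gave the same 9 calls as the main fit, so the alternatives are not all distinct checks. Main counts were 9 genes past adjusted p, 65 genes at least 2-fold apart on both arrays and 10 lists. With normexp offset 10 the first 2 were 63 and 103, on Agilent processed signals 115 and 150, and the authors' value table gave 34 and 147. An intensity trend in eBayes gave 97 genes past adjusted p. Unturned arrays, a contrast of the dyes, gave 0 genes in limma (29 at an unadjusted p under 0.05), 0 at 2-fold and 1 list. Lists past adjusted p were 5 with median centring, 0 with an estimated correlation and 0 with fry. With each array alone, 104 to 325 genes were at least 2-fold apart, by construction since only 1 array had to pass; the other counts have no test there. Aquantile leaves ratios as they are by construction. With both arrays, signs reversed for some lists and genes. With offset 10 the RpoS list came to 0.013 and type 1 fimbriae to 0.0045. Without background correction poly-N-acetylglucosamine came to 0.0079, cydA to -0.022 and edd to -0.0010. On processed signals anaerobic respiration came to 0.0296, RpoS to 0.0715 and fimbriae to 0.0895, and in the authors' values to 0.0356, 0.0715 and 0.0891. With median centring colanic acid came to 0.15, poly-N-acetylglucosamine to 0.15, fimbriae to 0.13 and cydA to -0.024. With the brightest probe iron uptake came to -0.0097, fimbriae to 0.071, icd to -0.0018, cydA to -0.071 and pfkA to -0.066. Without the genes from rluA to cra, the branched-chain list came to 0.070, by construction since 6 of its 13 genes left. The cause of the other changes was not tested. With both arrays, 929 values for genes and 298 for lists kept direction and side of the threshold, while 144 for genes gained a call, and 11 for genes and 36 for lists lost it. On array 1 alone the sign differed from the mean for 3 of 91 genes and 2 of 25 lists, among them the RpoS list at 0.18. On array 2 alone it differed for 3 genes (icd at -0.30, groS at -0.33 and mraZ at -0.06) and 3 lists, among them cold shock at -0.04 and biofilm regulators at -0.0044. Signal over background limits the wild type on array 1, where 54.8% of gene probes were well above it.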

Other observations

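The groups in this paragraph were chosen after their values were seen, as were all tests below. The thiamine synthesis genes thiC, thiE, thiF, thiS, thiG and thiH, which lie in an operon, had ratios of 1.56 ± 0.54, 2.15 ± 0.52, 2.15 ± 0.51, 2.07 ± 0.45, 1.83 ± 0.42 and 1.63 ± 0.64, and none passed in limma. The wild-type signals of these genes other than thiS were not well above background on array 1. Each of the 6 passed in 4 of 12 alternatives, and thiE ran to 4.04. Of other thi genes, thiB, thiP and thiQ lie in the stretch from rluA to cra and had means of -0.68, -0.52 and -0.38. In the mutant thiP and thiQ were not well above background on either array. In the propionate operon prpE rose by 2.20 ± 0.09, while prpC at 2.04 ± 0.39, prpD at 1.87 ± 0.22 and prpB at 1.25 ± 0.14 did not pass, though they did in 3, 4 and 2 of 12 alternatives. The iron-sulfur cluster genes iscX, hscA and fdx had 1.08 ± 0.05, 1.10 ± 0.11 and 1.17 ± 0.02.

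Also not past the test were ycgZ at -1.51 ± 0.26, ymgA at -1.14 ± 0.02 and ariR at -1.16 ± 0.21, neighbours on the chromosome of which ariR is known as a regulator of acid resistance. The envelope stress gene cpxP had 1.64 ± 0.45. Subunit genes of the second nitrate reductase, narV and narY, had 1.17 ± 0.19 and 1.19 ± 0.13, the glutamate synthase gene gltD had 1.16 ± 0.01 and the glucose dehydrogenase gene gcd had -1.19 ± 0.15. In 3 of 12 alternatives each, ycgZ, cpxP, narY and gltD passed.

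The 21 measured genes from rluA to cra, 29.3 kb, had a median ratio of -0.69 (-0.68 with undetected genes at their bounds, -1.42 with an offset of 10, -3.07 on the processed signals and -3.07 in the value table), and no window of as many genes apart from this stretch had all means below 0. The median at the bounds is no separate check, since the bounds lie close to the ratios. Dim signal is argued against, since genes matched on wild-type level had a median of -0.0203. Of 10000 matched sets 0 were as low, but their genes were drawn singly, without neighbours. The ends of the stretch were set after its ratios were seen, which partly fixes this count and that of the windows. The lowest median of windows apart from the stretch was -0.37. DNA of the stretch missing from the mutant strain is a candidate explanation: of 6 intergenic probes above background in the wild type on array 1, 5 were not above it in the mutant, against 32 of 986 elsewhere (Fisher's exact test, 2-sided, p = 3.2e-07, probes not being independent). It is not settled for rluA, rapA and polB, of whose 8 probes 6 stayed above background in the mutant on both arrays, since 1 of 3 probes of the deleted cra did so too. Between polB and cra, 14 of 15 gene probes above background in the wild type on array 1 were not above it in the mutant. Yet 2 of the 46 gene probes there were above background in the mutant on both arrays, as were 2 of the 18 intergenic probes of the stretch. Lower transcription of the stretch with its DNA present, through loss of Cra or otherwise, stays open, as RNA arrays measure no DNA. If its DNA is missing, differences elsewhere, such as those of the curli genes, cannot be told apart from effects of losing its other genes.

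The curli genes csgA, csgB and csgG had ratios that differed between the arrays by a median of 2.36. A dye effect alone is argued against, since the mean of both channels differed by -6.39 spreads of genes of like level, where such an effect would leave it in place. A dim wild-type dye on array 1 would shrink other low ratios too, but 9 other genes at least 4-fold lower differed by a median of -0.0365, from -1.27 to 0.69. Those were csgC, csgD, csgE, yceQ, and leuD, yabI, setA, rapA and rluA of the stretch above, so they form no independent set. In the mutant leuD and setA were not well above background, and csgF, which missed the 4-fold cut, differed by 0.94. The test therefore does not settle this explanation. Wild-type samples differing in these transcripts are a candidate explanation: the wild-type channel differed by a median of -4.32 spreads, with -3.79 for csgA, -4.38 for csgB and -4.32 for csgG, while the mutant channel did not widen the gap by more than its spread. The mutant channel differed too, by a median of -3.71 spreads, with -3.71 for csgA, -5.74 for csgB and 0.363 for csgG. Other curli genes shifted as well. In the mutant channel csgC, csgE and csgF differed by -6.55, -4.42 and -6.13 spreads, and csgD by -1.40. In the wild-type channel they differed by -2.96, -0.94 and -3.74, and csgD by 0.60. A difference in the wild type only does not cover both channels. Differing cultures, labelling or biology were not tested.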
